A study of Mus musculus with 2 samples.

How the data were processed

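H3K9me3 ChIP-seq of mouse facial prominences at embryonic day 10.5 was represented by 4 deposited peak lists: one for each of the 2 biological replicates, one called on both replicates together and one of replicated peaks. Each replicate was a pool of embryos of both sexes, 69 and 51 of them, of strain B6NCrl, with a library size range of 300 to 500 given in the labels. The coordinates are on mm10, per the labels. The peak caller, the aligner and the rule behind the replicated list are not given in the sources used here. No control library was analysed here.

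The deposited lists are in narrowPeak format, per the descriptions deposited with them. Each peak has a display score, set by the authors' caller and not used here beyond a check of its range. It has a fold enrichment, a linear ratio from the authors' caller, and a −log10 p and a −log10 q, also from the authors' caller. The smallest −log10 p was 2.0 in each of the 4 deposited lists. These are the peak's own values, and they were used only to describe, rank or filter peaks within a list. Many replicate 2 peaks had a −log10 q near 0 (median 0.458, against 1.54 in replicate 1), so the replicate lists include peaks that a filter on q would remove. The depth is unknown, since the files hold no read counts. A larger or deeper library gives more and wider peaks, so numbers of peaks and covered bases are not compared between replicates as amounts of the mark. The 95% Wilson intervals of overlap treat peaks as independent and cover counting error only.

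Genes, exons and TSSs came from GENCODE M21 and sequence from GRCm38.p6, the assembly that mm10 is built on. Chromosomes 1 to 19 and X were analysed; peaks on Y and on unplaced scaffolds are described separately. For gene lists and families, one gene model per symbol, the longest, was used. Genomic features used all 53843 annotated genes, of every biotype, and the exons of all their transcripts. A peak was assigned to a gene body by at least 1 base, and to a TSS or 3′ end by a window of 1 kb on each side. Each base was given the first feature that applied among promoter, exon, intron and intergenic, and soft-masked bases of the assembly stood for repeats. Primer binding sites were exact 18-base matches on either strand to the complements of 7 tRNA 3′ ends. The tRNA-Leu sequence (TGGTGTCAGGAGTGGGAT) had 0 matches.

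With 1 group of 2 replicates no test between groups was possible, and p-values across genes were not computed. The background was the same peak list shifted by a random distance around each chromosome from 3 Mb on, which keeps peak widths, spacing and number per chromosome. A count or share was called above or below this background when outside the central 95% (percentiles 2.5 to 97.5) of 1000 such rotations. For replicate overlap 100 were used, and for features under other settings 200. About 1 in 20 lists falls outside by chance. Values of each replicate's own list were computed for the peak lists, chromosomes, features, gene lists, primer binding sites and dense windows, and are given for the main results; gene families were tested in the replicated list alone.

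The 16 gene lists were fixed before the data were examined: zinc finger (Zfp) genes, olfactory receptors, vomeronasal receptors, clustered protocadherins, Hox genes, tandem families of adult organs, imprinted genes, germline genes, craniofacial regulators, housekeeping genes, neuronal, blood and endothelial, muscle, epithelial, and liver and gut genes, and H3K9me3 machinery. The symbols Villin and Tasor were not found in the annotation. Pax7, Trp63, Zfp57 and Zfp809 each stand on a pair of lists. The rule for named genes was also fixed beforehand. It took, per list, up to 4 genes with the most covered bases among those overlapped in both replicates' own lists. For regulators, germline and imprinted genes it added up to 4 with the highest fold enrichment within 1 kb of the TSS. Of all protein-coding genes it took the 10 highest by fold enrichment at the TSS and the 5 with the most covered bases, and of peaks the 5 highest by fold enrichment and the 5 widest. Genes of the 10 densest windows of 1 Mb were given as families.

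The list test was tested on simulated data. Peaks planted at the TSSs of 30% of 40 random genes on rotated peak lists gave a call above the range in 20 of 20 trials, and peaks at 10% did in 9 of 20. The 16 real lists on rotated peaks, 320 trials, gave 9 calls above and 3 below (3.75%). Those peaks were rotated in the same way as the background, so a low rate was given by construction. All these trials used the TSS window and none the gene body. Overlap and coverage functions were checked against direct counting. Alternatives were a −log10 q of at least 2, fold enrichment at or above the list's median, peaks of 500 bp or more, the jointly called list, each replicate's own list, other overlap rules, windows of 5 kb, windows of 500 kb, all biotypes, at least 500 covered bases, and 10000 random lists matched on gene length. One more was chosen after seeing the data, the 40565 replicated peaks that overlap both replicates' own lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.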

Results

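H3K9me3, histone H3 trimethylated on lysine 9, is the histone mark of constitutive heterochromatin and of silenced genes and retroelements. It was mapped by ChIP-seq, in which chromatin fragments bound by an antibody are sequenced, in the facial prominences of mouse embryos on day 10.5 of development. The facial prominences are the outgrowths of mesenchyme and surface epithelium that form the face and jaws. The data were 2 biological replicates of 1 group. Replicate 1 was tissue pooled from 69 embryos of both sexes and replicate 2 from 51. No second tissue, stage or mark was in the data, so the comparisons below are between the replicates and between classes of genes and sequence within the lists. Read depth was unknown, since the lists hold peaks only.

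The authors called 172831 peaks in replicate 1, which covered 39.6 Mb or 1.54% of chromosomes 1 to 19 and X. Replicate 2 had 110925 peaks over 15.04 Mb, or 0.584%. Peaks of replicate 1 were wider, with a median of 163 bp against 107 bp, and 38.8% of them reached a −log10 q of 2, against 11.4% in replicate 2. The list called on both replicates together held 113608 peaks. A replicated list of 49767 peaks, with a median width of 377 bp, covered 24.7 Mb or 0.960%, and 93.5% of its peaks reached a −log10 q of 2. Unless another list is named, the values below are from the replicated list.

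H3K9me3 peaks in the highest class of fold enrichment were shared by the replicates more often than those in the lowest. At least 1 base of 24.9% of replicate 1 peaks (42821 of 171952; 95% Wilson interval 24.7% to 25.1%) was overlapped by a replicate 2 peak. Rotated lists gave a mean of 1.70% and at most 2.34%. In the other direction, 47.2% of replicate 2 peaks (51992 of 110140; 46.9% to 47.5%) were overlapped by replicate 1, against a mean of 2.79% and at most 3.92% in rotations. Overlap was 11.96% in the lowest of 10 equal classes of replicate 1 by fold enrichment, 42.0% in the second highest and 70.9% in the highest. For replicate 2, these shares were 34.2%, 64.5% and 84.3%. Where the overlap had to span at least 0.5 of both peaks, 7.71% of replicate 1 and 12.0% of replicate 2 peaks were shared. When both lists were limited to peaks of a −log10 q of 2 or more, 11.6% of replicate 1 and 74.2% of replicate 2 peaks were, and when limited to 500 bp or more, 8.55% and 93.0%. The limited lists were unequal, with 66515 and 12167 peaks by q and 11344 and 1242 by width. The short list of replicate 2 limits the share that replicate 1 can reach.

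**Figure D1:**
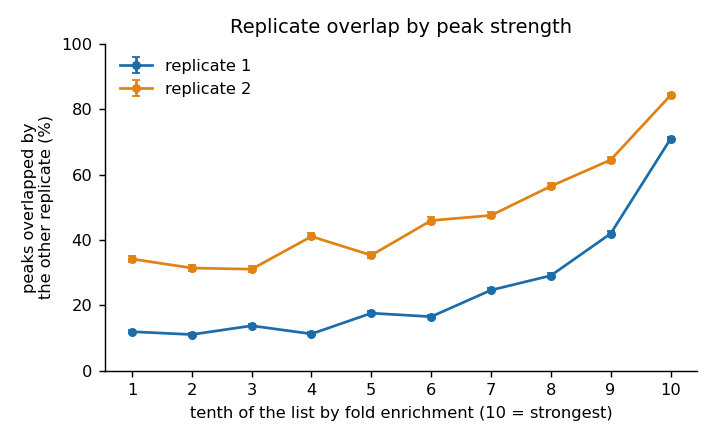
The share of each replicate's peaks overlapped by at least 1 base of the other replicate's list (y axis, percent) in 10 equal classes of fold enrichment (x axis, 10 the strongest). Bars are 95% Wilson intervals; the share is 70.9% in the strongest class of replicate 1 and 84.3% in that of replicate 2.

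The whole replicated list was contained in the list called on both replicates together. Of those jointly called peaks, 40309 overlapped a peak of each replicate by at least 0.5 of either peak's length, and all of them were in the replicated list. They made up 81.0% of it. With 1 base as the criterion, 81.5% of the replicated peaks overlapped both replicates' own lists, 16.5% only that of replicate 1, 1.75% only that of replicate 2 and 0.291% neither. The criterion by which these others entered the list is not given in the sources used here.

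H3K9me3 was concentrated on a few chromosomes. Chromosome 7 carried 16.4% of the replicated peaks on the 20 chromosomes analysed, and its covered bases, 31.9 kb per Mb, were 3.83 times those of the median autosome (8.33 kb per Mb). The ratio was 3.025 in replicate 1 and 3.023 in replicate 2. Chromosome 17 followed at 2.32 times and chromosome 4 at 1.54 times, while chromosome 1 lay at 0.540. Chromosome X was at 0.499 in the replicated list. The replicates differed there, with 0.950 in replicate 1 and 0.525 in replicate 2. Of the sequence of X, 46.8% was soft-masked, against at most 35.8% on an autosome. The ratio allows neither for this nor for the copies of X in pools of both sexes. It therefore does not measure the level of the mark on X.

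**Figure D2:**
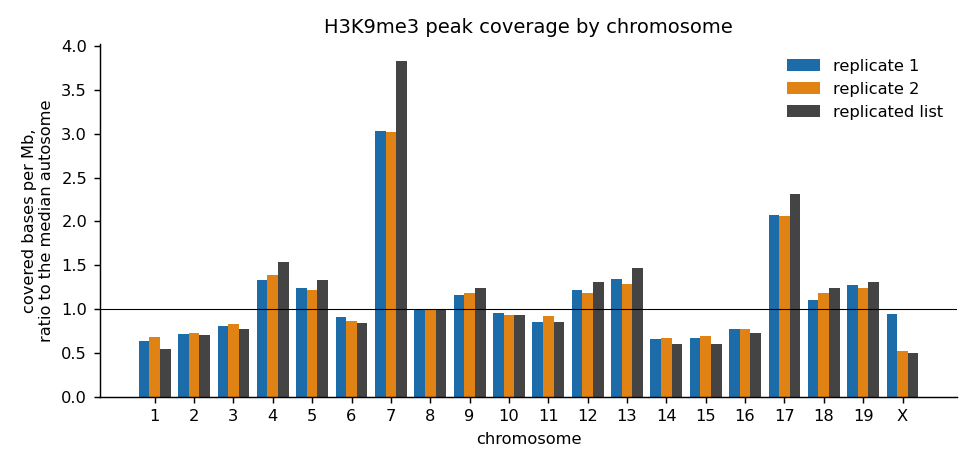
Covered bases per Mb of each chromosome as a ratio to the median autosome (y axis) for replicate 1, replicate 2 and the replicated list. Chromosome 7 stands highest, at 3.83 in the replicated list, and X is the chromosome on which the replicates lie apart, at 0.950 and 0.525.

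Most of the 10 densest windows of 1 Mb held arrays of clustered gene families, as read from gene symbols and not tested. Among 2585 windows of 1 Mb, the median held 3.79 kb of peaks, 81 held none, and the 10 densest held 10.1% of all covered bases. The first was chromosome 18, 37000001 to 38000000, with 330 kb under peaks in the replicated list (340 kb in replicate 1, 171 kb in replicate 2), which contains the clustered protocadherins, adhesion proteins of neurons. The second, chromosome 13, 61000001 to 62000000 (281 kb), held a cathepsin array of the Cts family, and the third, chromosome 7, 33000001 to 34000000 (264 kb), a secretoglobin array. A window of chromosome 12, 114000001 to 115000000 (256 kb), had 0 protein-coding genes and 49 immunoglobulin variable genes. Of the other 6, 5 were on chromosome 7. These held 9, 5, 12 and 18 vomeronasal receptor genes in the windows that start at 10, 42, 12 and 23 Mb, and Psg and Ceacam genes in the window that starts at 17 Mb. The windows that start at 42 and 12 Mb also held 4 and 7 zinc finger (Zfp) genes. The remaining window, chromosome 4, 121000001 to 122000000, had 210 kb under peaks and 8 protein-coding genes. With windows of 500 kb, 6 of these 10 were again among the densest.

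By genomic feature, covered bases lay in promoters and exons more often than in rotated lists and in introns less often. Features were drawn from annotated genes of all biotypes, not from protein-coding genes alone. Promoters, the 1 kb on each side of a transcription start site (TSS), held 7.08% of covered bases against a rotation mean of 4.22% (1.68 times). Exons held 6.73% against 4.29% (1.57 times) and introns 30.1% against 41.6% (0.723 times). Intergenic sequence held most of the covered bases, 56.1% against 49.9% (1.12 times). These 4 lay outside the central 95% of 1000 rotations in the replicated list and in each replicate's own. Intergenic sequence was within it, at 1.03 times, when promoters were widened to 5 kb. Soft-masked repeats held 35.4% against 33.8%, within the central 95%. In replicate 1 they held more than rotated lists (1.07 times) and in replicate 2 fewer (0.941 times). How reads with several placements were treated is not given in the sources used here, and rotation does not allow for it. These shares therefore do not settle whether repeats carry more of the mark.

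Among 16 gene lists fixed beforehand, 6 had a peak in the gene body more often than rotated lists. They were the zinc finger genes, vomeronasal receptors, clustered protocadherins, tandem adult-organ families, imprinted genes and germline genes. Of all 21727 protein-coding genes, 23.9% had a peak in the body and 4.16% within 1 kb of the TSS. In each replicate's own, longer list the excess over rotation was smaller, for example 1.53 and 1.62 times in place of 2.43 times for zinc finger genes. All 6 lists stayed above the range in both, except the tandem families, which were within it in replicate 1 (91 of 287 genes, rotation mean 70.7).

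**Figure D3:**
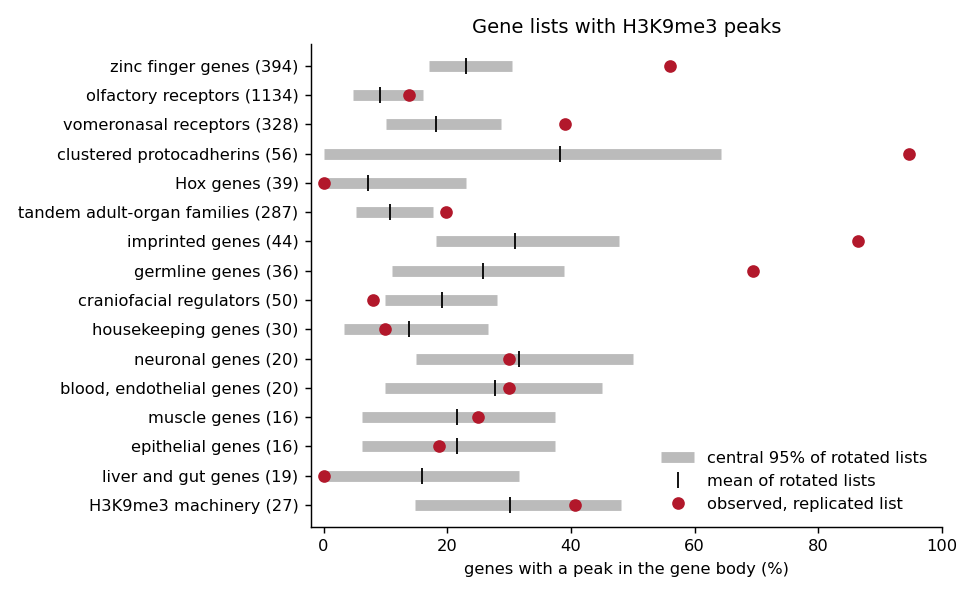
The share of genes of each list with a replicated peak in the gene body (x axis, percent; red points), with the mean (tick) and central 95% (grey bar) of 1000 rotated lists; list sizes are in brackets. Protocadherins (94.6%), imprinted genes (86.4%), germline genes (69.4%) and zinc finger genes (56.1%) lie farthest above their ranges and craniofacial regulators (8.0%) below theirs.

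Zinc finger genes, named Zfp in the annotation and many of them encoding DNA-binding repressors, carried a peak in the body in 221 of 394 cases, against a rotation mean of 90.8 and a central range of 67 to 120. Covered bases were most numerous in Zfp943 on chromosome 17 (21962552 to 22071168), of whose body 28.3% was covered. Zfp936 on chromosome 7 (38.6%), Zfp981 on chromosome 4 (58.9%) and Zfp180 on chromosome 7 (68.4%) followed, among genes overlapped in both replicates. In replicate 1, 69.3% of Zfp180 was covered, and in replicate 2 41.1%. A peak at chromosome 7, 24098766 to 24110034, which runs from within Zfp180 past its 3′ end, had an authors' fold enrichment of 14.5.

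The mark lay toward the 3′ ends of these genes. Within 1 kb of the 3′ end 133 of 394 had a peak (rotation mean 20.1, central range 8 to 39), and within 1 kb of the TSS 34 had one (20.3, 8 to 39.0, within the range). The TSS count was above the range in replicate 1 (94, range 27 to 73), in the jointly called list (68, 18 to 58), with 5 kb windows (120 genes) and against length-matched genes (8 to 23), and within it in replicate 2 (51, 18 to 53). A peak at the 3′ end and not at the TSS was found in 111 genes and the reverse in 12, a ratio of 9.25. For the other 21333 protein-coding genes the numbers were 575 and 511, a ratio of 1.13. In 20 equal bins along the gene, mean coverage was 1.45% in the first bin and 21.0% in bin 19, and these were 3.62% and 22.8% in replicate 1 and 1.11% and 12.1% in replicate 2. The ratio stayed above that of other genes in both replicates but was smaller, 3.41 in replicate 1 (116 and 34 genes) and 4.67 in replicate 2 (112 and 24). It was 4.65 in the jointly called list and 3.89 with windows of 5 kb.

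**Figure D4:**
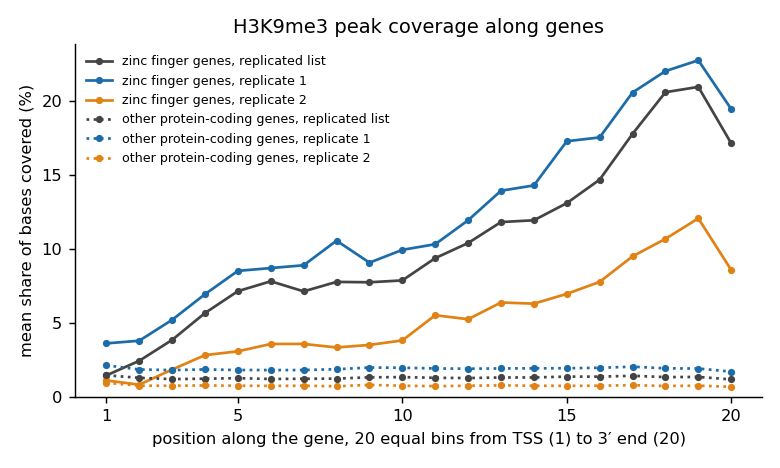
Mean share of bases under peaks (y axis, percent) in 20 equal bins from the TSS to the 3′ end of 393 zinc finger genes (solid lines) and 19782 other protein-coding genes (dotted lines) of at least 2 kb. Coverage of zinc finger genes in the replicated list is 1.45% in the first bin and 21.0% in bin 19.

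Clustered protocadherins had the highest share of marked genes. A peak lay in the body of 53 of 56 genes, against a rotation mean of 21.4 and a central range of 0 to 36. Within 1 kb of the TSS 53 had one, against a rotation mean of 1.44 and a central range of 0 to 5. The exceptions were Pcdhgc3, Pcdhgc4 and Pcdhgc5, named after their values were seen. In the jointly called list and in each replicate's own list, all 56 bodies had a peak. Pcdhga1 (chromosome 18, 37661793 to 37841873) had 104398 covered bases or 58.0% of its body, with 58.4% in replicate 1 and 38.3% in replicate 2. Pcdhga2, Pcdhga3 and Pcdhgb1 were covered over 58.0%, 56.9% and 55.4%. These genes share their last exons and their bodies overlap, so they are not independent. Of the 10 protein-coding genes with the highest fold enrichment at the TSS, 8 were gamma protocadherins, Pcdhga8, Pcdhga9, Pcdhga11, Pcdhga12, Pcdhgb4, Pcdhgb5, Pcdhgb6 and Pcdhgb7, at 11.7 to 13.8. These were not 8 separate peaks, since neighbours shared them. Pcdhga9, Pcdhgb5 and Pcdhgb6, for example, had the same one (37731390 to 37742398). Of the 5 genes with the most covered bases, Pcdhga1 and Pcdhga2 were joined by Gm42416, Gm37013 and Gm37388, gene models that span the array, with 353558, 343323 and 340915 bases.

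Imprinted genes, expressed from the maternal or the paternal allele alone, were marked in 38 of 44 bodies (rotation mean 13.6, central range 8 to 21) and at 24 of 44 TSSs (2.51, 0 to 8). Among the 44 listed genes, the highest fold enrichment at a TSS was 10.3, of a single peak (chromosome 7, 6727012 to 6731281) shared by the start sites of Peg3 and Usp29. Nespas, an antisense transcript of the Gnas locus, had a peak of 10.01 (chromosome 2, 174294351 to 174301331), and Airn, antisense to Igf2r, one of 8.20 (chromosome 17, 12740309 to 12744419). The most covered bases were in Kcnq1 (16244), Snrpn (14911), Kcnq1ot1 (14156), which lies antisense within Kcnq1, and Airn (13802). At TSSs, 27 of the 44 had a peak in replicate 1 and 23 in replicate 2. Several members share a locus and hence a peak.

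Germline genes, needed for meiosis or germ cell development, were marked at the promoter. A peak lay within 1 kb of the TSS in 19 of 36 (rotation mean 1.28, central range 0 to 4), and in the body in 25 (9.28, 4 to 14). In replicate 1, 25 TSSs had a peak, and in replicate 2 18. Fold enrichment at the TSS was highest at Ddx4, a germ cell RNA helicase (9.35; chromosome 13, 112651683 to 112652807), Dazl, a germ cell RNA-binding protein (7.93; chromosome 17, 50293055 to 50294594), Taf7l (5.91; chromosome X, 134474669 to 134476530) and Stag3, a meiotic cohesin subunit (5.58; chromosome 5, 138280366 to 138281309). The most covered bases were in Taf7l (1822), Meioc (1551), Piwil1 (1086) and Tdrd1 (1026). At the 3′ end 1 of 36 had a peak, within the range.

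Receptor and adult-organ gene arrays were marked to different degrees. Of 328 vomeronasal (pheromone) receptors, 128 had a peak in the body (rotation mean 59.8, central range 33 to 94) and 54 at the TSS (21.5, 6 to 48.0). Vmn2r60, Vmn2r59, Vmn2r53 and Vmn2r61, all on chromosome 7, were covered over 27.1%, 33.0%, 32.5% and 32.6% of their bodies. At the TSS 96 had one in replicate 1 and 73 in replicate 2, both above the range. The TSS count was within the range when peaks were limited to those of 500 bp or more (27, 1.98 to 27) or to those above the median fold enrichment (31, 3 to 35). Of 1134 olfactory receptors, 156 had a peak in the body (104, 54.0 to 182, within the range). The most covered bases were in Olfr1349 (78.6% of the body), Olfr398 (60.4%), Olfr406 (44.9%) and Olfr1347 (38.0%). Against random genes of matched length, the olfactory count was above the range, at 1.44 times. At the 3′ end 129 olfactory receptors had a peak, above the range (rotation mean 52.2, upper end 110), except with peaks above the median fold enrichment (75, 9 to 78). At the TSS 89 had one (52.6, 19 to 109, within the range), while 199 in replicate 1 (range 68 to 198) and 150 in replicate 2 (49 to 145) lay just above it. Of 287 genes in tandem families of adult organs, such as cytochromes P450 and glucuronosyltransferases, 57 had a peak in the body (31.0, 15 to 51) and 26 at the TSS (10.7, 3 to 24), with 62 in replicate 1 and 38 in replicate 2, both above the range. The TSS call was lost with peaks of 500 bp or more (11, 0 to 12) and with all biotypes (28, 3 to 30). Cyp3a57, Cyp2c29, Cyp3a11 and Ugt1a7c were covered over 37.5%, 23.2%, 48.8% and 9.77%.

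Craniofacial regulators were mostly without peaks. Of 50, 4 had a peak in the body against a rotation mean of 9.59 (central range 5 to 14.0, below it), and 0 had one at the TSS (mean 1.62, within the range). Within 5 kb of the TSS 0 had one as well, which was below the range (mean 4.95, 1 to 9). The 4 were Runx2 (1801 covered bases), Pax7 (570), Twist2 (475) and Ednra (395), each covered over 0.565% to 1.02% of the body. Sox9, a regulator of cartilage named after its values were seen, had no peak in its body in the replicated list or in either replicate. The call rests on few genes. In replicate 1's own list 17 of 50 had a peak (mean 20.2) and in replicate 2's 13 (17.8), both within the range.

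None of the 39 Hox genes, regulators of position along the body axis, had a peak in the replicated list (rotation mean 2.83, central range 0 to 9), while 3 had one in replicate 1 and 6 in replicate 2. Other lists were within their ranges. Housekeeping genes had a peak in 3 of 30 (Tbp, Hprt and Rpl3), neuronal genes in 6 of 20 (Slc17a7, Nefm, Syt1 and Rbfox3 the most), and blood and endothelial genes in 6 of 20 (Runx1, Fli1, Tek and Erg the most). Muscle genes had one in 4 of 16 (Ttn, Ckm, Pax7 and Tnnt1), epithelial genes in 3 of 16 (Dsp, Cdh1 and Grhl2), and liver and gut genes in 0 of 19 (mean 3.01, range 0 to 6). The genes listed as H3K9me3 machinery had one in 11 of 27, among them Atf7ip (5844 covered bases), Trim28 (1293), Zfp809 (1241) and Morc2a (1106). At the TSS they were within the range in the replicated list (2 of 27) and in replicate 2 (3 of 27, mean 1.88), and above it in replicate 1 (8 of 27, mean 2.82) and the jointly called list (6 of 27, mean 2.04).

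Retroelements were found by exact matches to 18-base primer binding sites, where a tRNA primes reverse transcription beside the 5′ long terminal repeat. All 6 classes with matches in the genome had a replicated peak within 1 kb more often than rotated lists. The share was 62.5% of 64 tRNA-Lys1,2 sites (TGGCGCCCAACGTGGGGC; rotation mean 4.01%), 53.4% of 146 tRNA-Pro sites (TGGGGGCTCGTCCGGGAT; 3.69%) and 45.0% of 60 tRNA-Lys3 sites (TGGCGCCCGAACAGGGAC; 3.90%). It was 31.8% of 1068 tRNA-Phe sites (TGGTGCCGAAACCCGGGA; 3.62%), 18.5% of 92 tRNA-Gln sites (TGGAGGTCCCACCGAGAT; 3.70%) and 13.3% of 195 tRNA-Gly sites (TGGTGCATTGGCCGGGAA; 3.95%). In replicate 1 the tRNA-Phe share was 59.1% and in replicate 2 35.7%, against rotation means of 9.70% and 6.59%. All 6 classes were above the range in both replicates, at 2.94 to 8.20 times the rotation mean in replicate 1 and 2.26 to 8.54 times in replicate 2. A peak lay over the site itself in 3.28% of tRNA-Phe sites, 3.31 times the rotation mean against 8.81 times within 1 kb. For tRNA-Pro sites it did in 16.4%, 17.6 times the rotation mean against 14.5 times. The tRNA-Gly class was within the range when peaks below the median fold enrichment were left out (9 sites).

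**Figure D5:**
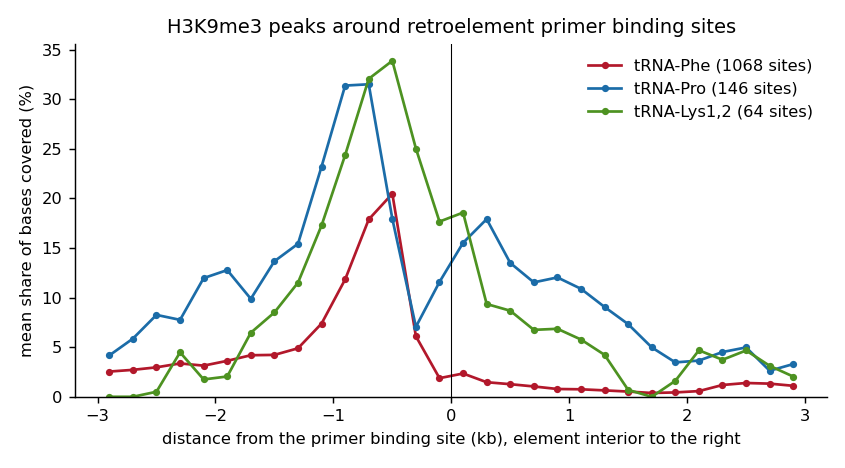
Mean share of bases under replicated peaks (y axis, percent) in 200-base steps around exact primer binding sites of 3 classes (x axis, kb; the element's interior is to the right). For tRNA-Phe the highest step, 20.5%, lies 600 to 400 bases before the site, and the step from 400 to 600 bases after it holds 1.27%.

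The 5 peaks with the highest authors' fold enrichment lay on 5 chromosomes. They were in an exon of Shroom3, an actin-binding regulator of cell shape (chromosome 5, 92939918 to 92943354; fold 15.1), over Klf14, an imprinted single-exon transcription factor gene (chromosome 6, 30956157 to 30958856; 14.7), across the TSS of Tcfl5, of whose body it covers 47 bp (chromosome 2, 180642662 to 180644329; 14.6), in Zfp180 (14.5) and in an exon of Zfp810 (chromosome 9, 22276592 to 22281113; 14.4). Klf14 was covered over 88.4% of its length, with 92.1% in replicate 1 and 69.9% in replicate 2. The widest peak, 26372 bp on chromosome 1 (88225422 to 88251793), had its midpoint in an exon of Mroh2a. Of the next 4 by width, 3 lay in Zfp110, Zfp606 and Zfp180 on chromosome 7. The fourth, 12944 bp on chromosome 3 (3021108 to 3034051), lies beside the assembly gap at the start of that chromosome.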

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

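Chromosome Y and the unplaced scaffolds were outside the comparisons above, and both carried peaks beyond the 3 that a count of 0 allows. The replicated list had 32 peaks on Y, where replicate 1 had 197 and replicate 2 had 58. It had 360 peaks on 27 unplaced or unlocalized scaffolds, with 682 in replicate 1 and 727 in replicate 2, although replicate 1 had more peaks than replicate 2 on the 20 chromosomes analysed. The median fold enrichment of the scaffold peaks was 3.90, against 3.45 on those chromosomes. The scaffold with the most replicated peaks was JH584304, with 89. No explanation of these values was tested.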

How the results depend on the processing

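No paired analysis was possible because the samples form 1 group. Of the 289 values recomputed for the main results under the alternatives, 251 kept their call against the range or moved by less than the spread, and 13 of these lay within the range on the other side of the background mean. The value that reversed was that of soft-masked bases without replicate 1. The replicated peaks found in both replicates' own lists were an alternative chosen after seeing the data. Depth limits which weak peaks were called at all, and it is unknown. Where no cause is named below, the cause was not tested.

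Ranked by −log10 q, overlap in the lowest and highest classes was 8.54% and 72.6% for replicate 1 and 26.2% and 86.5% for replicate 2. Relative to the median autosome, chromosome 7 was at 3.92 with a −log10 q of 2 or more, 4.46 above the median fold enrichment, 4.35 with peaks of 500 bp or more, 3.23 in the jointly called list, 4.09 for peaks found in both replicates and 3.023 to 3.025 with either replicate left out. With a replicate left out, chromosome X ranged from 0.525 without replicate 1 to 0.950 without replicate 2. Under the other alternatives it lay between 0.381 (500 bp peaks) and 0.631 (the jointly called list). Soft-masked bases were above the range in the jointly called list (1.05 times) and at 1.047 with promoters of 5 kb, where the promoter does not enter and a range from 200 rotations replaced that from 1000. With a replicate left out they ranged from 0.941, below the range without replicate 1, to 1.07, above it without replicate 2, and the main value (1.046) was within it. Intergenic bases were within the range, at 1.03, with promoters of 5 kb, which take bases from them by construction.

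The low count of craniofacial regulators was within the range above the median fold enrichment (0.338 times rotation), with 500 bp peaks (0.230), in the jointly called list (0.739), with peaks found in both replicates (0.476), with at least 500 covered bases (0.360) and with either replicate left out (0.730 to 0.842). Hox genes, at 0 in each case, were below the range in the jointly called list and against length-matched genes. Olfactory receptors were above it against length-matched genes (1.44). Tandem adult-organ families fell within it without replicate 2 (1.29) and stayed above it without replicate 1 (1.47). The tRNA-Gly sites fell within the range above the median fold enrichment (1.96). For single places of a list (the TSS), 11 of 150 recomputed values moved outside the range and 4 moved into it.

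The ratio of zinc finger genes with a peak only at the 3′ end to those with one only at the TSS was 10.3 with a −log10 q of 2 or more, 13.6 above the median fold enrichment, 12.1 with 500 bp peaks, 11.1 with peaks found in both replicates, 4.65 in the jointly called list, 3.89 with 5 kb windows and 3.41 to 4.67 with a replicate left out. Of the 10 densest windows, 6 were shared when windows were 500 kb.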

Other observations

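The tests of the dense neighbourhoods of zinc finger genes, of the sex of the embryos and of gene families were chosen only after the result was seen. Among 278 families of at least 10 genes that share the start of their symbols, 9 had a peak in the gene body more often than the central range of rotated lists. Besides the beta protocadherins (Pcdhb, 22 of 22) and the zinc finger and vomeronasal genes described above, these were Ighv, immunoglobulin heavy chain variable genes that are rearranged in B cells (52 of 113, rotation mean 1.81), Nlrp, several of which act in the oocyte (12 of 17, 6.37), Skint (10 of 11, 5.04), Klra, receptors of natural killer cells (7 of 11, 1.67), Cyp (40 of 100, 22.8) and Tex, testis-expressed genes (11 of 38, 6.34). Of the bases of the Ighv genes, 30.5% lay under peaks. The Tex count was just above its range (upper end 10). Peaks covered 0.362% of the bases of Tex, less than the 0.960% of the chromosomes analysed. The alpha (Pcdha, 11 of 11, rotation mean 8.27, range 0 to 11) and gamma A protocadherins (Pcdhga, 12 of 12, 7.08, 0 to 12) were within their ranges. Each range reached the size of the family, so neither could be called above it. Peaks covered 20.9% of the bases of Pcdha and 46.3% of those of Pcdhga. Families below the range were Car, the carbonic anhydrases (0 of 16, 3.52), Kdm, mostly histone demethylases (2 of 17, 6.49) and Fam (40 of 203, 53.2). A family whose range starts at 0 could not be called below it, so these 3 are not set against a chance share. The immunoglobulin kappa variable genes, Igkv, had a peak in 0 of 100 (1.43, within the range), unlike Ighv, a difference that was not tested.

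A hypothesis is that tandem arrays of genes used in other tissues may carry H3K9me3 as a rule. Over all 278 families, 3.24% lay above the range, close to the 2.5% that chance gives on that side at most, but most of these families are not arrays. The test was then narrowed in steps, each after a share was seen, to families with at least 80% of their genes on 1 chromosome (4 of 33, 12.1%) and to those of them with no gene on a fixed list, and a condition on the interval was also set after that. In the last step 3 of 23 lay above the range (13.04%; 95% Wilson interval 4.54% to 32.1%), too few to decide. The secretoglobins (11 of 34, range 0 to 13) and the Psg genes (9 of 13, 0 to 11) were within their ranges.

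Zinc finger genes had peaks at the 3′ end and not at the TSS 9.25 times as often as the reverse. Dense neighbourhoods that mark both ends alike are argued against by a ratio of 22.5 (95% interval 8.58 to 59.0) among 222 genes with another within 100 kb, but the pattern was weaker in the 172 genes with no other that near (21 against 8, ratio 2.63, 1.19 to 5.80), so a part that clustering plays stays open. Reads shared between the 3′ ends of the listed genes are argued against, as the whole cause, by a ratio of 9.18 (4.98 to 16.9). This was found among 356 genes whose last 1 kb shared under 10% of its 36-base words with the last 1 kb of another listed gene. Copies elsewhere in the genome were not searched, so reads shared with those stay open. The 95% intervals of these ratios treat genes as independent. Neighbouring genes can lie under the same peaks, so the intervals can be too narrow. A candidate explanation is the zinc finger array, encoded near the 3′ end, since genes with 5 or more TGEKP linkers, the residues that join fingers, had a 3′ end peak 5.11 times as often as those with none (96 of 176 against 11 of 103). Among genes with other names it was found in 30 of 82 with 5 or more linkers (36.6%) and in 4.22% of 21117 without, but a TSS peak was also more frequent in these (12.2% against 4.05%); the design has 1 group, so no biological cause of the mark was tested.

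Chromosome X carried 6.78% of the peaks of replicate 1 and 3.43% of those of replicate 2, a ratio of 1.98 (95% counting interval 1.91 to 2.05). A few loci do not account for it, since 94.5% of the 165 windows of 1 Mb on X with a peak had more replicate 1 peaks per replicate 2 peak than the autosomes as a whole, against at most 61.0% on any autosome. A larger share of female embryos in the pool of replicate 1 would lower Y, but relative to autosomes Y had 2.25 times as many peaks in replicate 1 (1.68 to 3.02), so that X and Y shifted the same way. The Y peaks were counted at all strengths, weak ones included, so this count cannot decide on the share of females. Weak peaks near the authors' threshold may carry the difference, with a ratio of 2.85 in the weaker 5 of 10 classes by fold enrichment and 1.08 (0.936 to 1.26) in the strongest. Many peaks had the same fold enrichment at the class limits, however, at 3.296 in replicate 1 and 3.016 in replicate 2. Such ties were split in chromosome order with X last, which placed tied X peaks in the stronger class. The ratios by class are therefore inexact and cannot decide whether weak peaks carry the difference. The sex ratio of the pools and the control used for each replicate are not known, and why the replicates differ on X stays open.

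In the kilobase inside the element after tRNA-Phe primer binding sites a mean of 13.4 bases lay under peaks, against 110 from 500 to 1500 bases before the site. Sequence inside the element that is shared between copies, so that reads are placed only in the flank, may account for this. A first test of it only restated the pattern and was replaced by one on the share of 32-base words found once in the genome, which at the median site was 3.51% inside and 91.6% before. At 60 sites with at least 50% of such words inside, 156 bases inside were covered, 31.9 times as many as at the other 1008 (95% bootstrap interval 16.6 to 62.2), and the ratio of bases before to inside was 0.530 (0.244 to 0.869), against 22.7 (14.99 to 38.6) at the others. These sites were not drawn at random, so a lower level of the mark in the more repeated copies stays open, and how reads with several placements were treated is not given in the sources used here.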
